A study of Homo sapiens with 12 samples.

How the data were processed

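RNA was measured in 12 libraries of SH-SY5Y cells, 3 for each of 4 tau constructs, 24 h after transfection. The libraries were made with a 3′ mRNA kit from 400 ng of RNA each, per the labels' protocols. The kit reads near the 3′ end of polyadenylated transcripts. Nothing in the labels says whether the replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

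The submitters' processing notes name STAR 2.5.3a, RSEM 1.2.31 and DESeq2 and the genome build GRCh38, with no role or order. The transform of the reads, the gene filter, the strand setting and the clustering method are not given in the sources used here. The deposited table holds 1676 genes and 3 kinds of value. The 12 library columns are a score: the authors standardised each gene over the 12 libraries, as the values show (the largest absolute gene mean was 5.7e-15 and the gene SD lay between 1.0000 and 1.0000). The values run from -2.58 to 3.06, where 12 libraries allow at most 3.18 on either side. The deposited fold changes are on the log2 scale, per the file headers, and range in size from 0.49 to 11.5 with a median of 1.36. The deposited adjusted p-value of each gene, per the file headers, lies between 4.6e-07 and 0.0499. A cluster number from 1 to 4 is also deposited.

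Standardising removed the level, the depth and the fold size of each gene. The depth of the libraries is therefore unknown, no interval or floor can be given, and large and small responses look alike. A pseudocount, a filter on low values, another scaling factor and a count model cannot be applied to such values. The contrast behind the fold change is not named in the header. Its sign was compared with 9 contrasts of the group means, and it matched the interaction in 1676 of 1676 genes, Tau-K174Q-S199E against Tau-S199E in 1672, and Tau-S199E against Tau-WT in 0. With the direction turned, Tau-WT against Tau-S199E matched in 1676 and Tau-WT against Tau-K174Q in 1675. The deposited adjusted p-values were therefore also compared with the absolute t of each contrast, a step chosen after the data were seen. The Spearman correlation was 0.59 for the interaction, 0.47 for Tau-S199E against Tau-WT and at most 0.37 for the other pairs of constructs, and the unadjusted limma p was 0.05 or more in 48 genes for the interaction and in 146 for Tau-S199E against Tau-WT.

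Groups come from the labels. The columns name the construct, a library number and a code of a letter and a digit, not the replicate number of a sample. Libraries are therefore named here by construct and library number: Tau-WT 1, 2 and 3, Tau-K174Q 4, 5 and 6, Tau-S199E 10, 11 and 12, and Tau-K174Q-S199E 16, 17 and 18. The meaning of the code is not stated. It runs in order with the library number except in Tau-WT library 1, which stands apart. If it marks a position, position and construct cannot be told apart. All columns of per-sample values were used.

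The plan made before the data were examined was a test of counts, or limma on log2 values, neither of which the unit allows. The standardised values were fitted as deposited with limma 3.58.1 (R 4.3.3) with a mean for each construct over all 12 libraries, and each contrast was tested by gene with its ordinary residual variance and Benjamini-Hochberg adjustment over the 1676 genes, threshold 0.05, two-sided. A test of this kind does not depend on the scale of a gene, whereas moderated variances assume that residual variances are alike, which standardising disturbs. limma's moderation gave a prior with infinite degrees of freedom on these values. The choice of the ordinary test was made after both had been run, on simulated data: with 200 of 1676 genes shifted in Tau-K174Q against Tau-WT by 4 residual SDs before standardising, the ordinary test recovered 82.5% with 9 false calls and the moderated one 0%. At 6 residual SDs they recovered 99.5% and 98%, and at 2 residual SDs 2.5% and 0%. In these simulated data most genes held no shift, whereas each gene of the deposited table was selected for an effect. The rates therefore need not hold for that table and do not settle which test suits it better. Counts by the moderated test are given beside the others.

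Because the table was inferred from this to be selected on the interaction, 20 tables were simulated in which each gene kept its own interaction statistic and all else was independent noise. The counts that both tests and the fit on 6 libraries make in these tables show what selection alone gives. They also hold the shared Tau-WT libraries. If each gene kept its statistic for Tau-S199E against Tau-WT instead, 20 simulated tables gave 443 to 568 genes for the interaction, against the observed 1625, and 452 to 623 for any construct, against the observed 566. The latter count therefore does not speak against that selection, while the former does if no other effect is present.

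Comparisons were each construct against Tau-WT, the constructs with each other, the interaction and a test over all 4 constructs. The 29 gene lists were fixed before the data were examined. For lists with at least 5 members in the table, camera with a preset correlation of 0.01 set the members against the rest of the table, with adjustment over the lists of a comparison, and camera with an estimated correlation and fry, which tests a list against no change and not against the rest of the table, were the alternatives. Since the genes that were tested but not listed are unknown, no enrichment of a list in the table was tested. The noradrenergic neuroblastoma and neuronal list, the synapse and ion channel list and the list of replication-dependent histones had 0 members in the table. MAPT was also compared by exact permutation tests.

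Genes were named by a rule fixed before the data were examined: MAPT, of genes past the threshold whose groups do not overlap the 10 largest rises and falls against Tau-WT and the 5 largest each way otherwise, up to 3 members with the smallest p of each list, and, where fewer than 5 genes passed, the 5 with the smallest p each way as values that did not pass. Size was taken in SD units, and for the interaction from the authors' deposited table. The criterion of the rule on mean expression could not be applied, and some genes that the rule names are not reported here. No gene passed in all 3 comparisons against Tau-WT.

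Symbols come from a table of gene names, which holds 1675 of the 1676 identifiers; 19 genes have no symbol and are not named. Positions, gene types and GC content (of the longest transcript) are from GENCODE 29 on GRCh38, which holds all 1676 identifiers. There were 1585 protein-coding genes and 46 pseudogenes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest. The alternatives tried were leaving out each library of the constructs compared, fitting only the libraries compared and moderated variances. Others were leaving out libraries 12 and 18, centring each library on its median, and protein-coding genes only.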

Results

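Polyadenylated RNA was measured in SH-SY5Y cells, an established human neuroblastoma line used as a model of neurons, 24 h after transfection with constructs encoding the microtubule-binding protein tau. The reference was wild-type tau (Tau-WT). Tau-K174Q and Tau-S199E carried 1 substitution each, and Tau-K174Q-S199E carried both. Replacing lysine by glutamine mimics an acetylated lysine and replacing serine by glutamate mimics a phosphorylated serine, so the K174Q-S199E construct carries a mimic of each modification in the same molecule. There were 3 libraries for each of the 4 constructs, 12 in all, made with a 3′ mRNA kit from 400 ng of RNA each. The deposited table lists 1676 genes, and its values are standardised: each gene has mean 0 and SD 1 over the 12 libraries. Differences below are therefore in SD units of each gene (SD units), not fold changes, and the depth of the libraries is unknown. The only fold changes are those of the authors' deposited table, on the log2 scale.

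The sign of the fold change in the authors' deposited table equalled the sign of the K174Q by S199E interaction, (K174Q-S199E minus S199E) minus (K174Q minus WT), in 1676 of 1676 genes, and all adjusted p-values in that table lay under 0.05, the highest being 0.0499. The header names neither the contrast nor its direction, and the sign of Tau-WT minus Tau-S199E matched as fully (1676 of 1676), so signs do not tell these contrasts apart. The order of the deposited adjusted p-values followed the absolute t of the interaction (Spearman correlation across genes 0.59) more closely than that of Tau-S199E against Tau-WT (0.47; difference 0.12, from 0.09 to 0.15 between the outer 2.5% of 1000 resamples of genes, which are not independent). Of 3000 random contrasts of the group means the one with the highest correlation, 0.59, had weights near those of the interaction: 0.52 for Tau-WT, -0.47 for Tau-K174Q, -0.53 for Tau-S199E and 0.48 for Tau-K174Q-S199E. The genes are therefore taken as selected on the interaction, which is an inference on which all statements on selection below rest. On this reading every gene listed is one in which the constructs with 1 substitution depart from the sum expected of Tau-WT and Tau-K174Q-S199E. Comparisons within the table are not independent of that selection. The contrasts of Tau-K174Q against Tau-S199E and Tau-K174Q-S199E against Tau-WT are orthogonal to the interaction. Their signs still equalled that of the interaction in 84.5% and 8.0% of the genes. Selection on the interaction alone would not set these signs. Selection on Tau-S199E against Tau-WT would favour both, through the group it shares with each contrast. Genes moved together, however, as the first principal component of the table held 74.9% of the variance. The signs are therefore not independent over genes. Each contrast also holds a library that lay apart from its group: library 12 of Tau-S199E and library 18 of Tau-K174Q-S199E. The signs thus cannot decide between selection on the interaction and selection on Tau-S199E against Tau-WT, and leave the inference less certain. No statement is possible on genes outside the table.

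The interaction asks whether the effect of K174Q depends on S199E. The genes with the smallest adjusted p in the authors' deposited table included AKT1, a kinase of growth factor signalling (log2 fold change -3.44, adjusted p = 4.6e-07), PFKM, a phosphofructokinase of glycolysis (-3.37, adjusted p = 4.6e-07), and PTPRF, a receptor tyrosine phosphatase (-2.22, adjusted p = 6.58e-07). These genes were picked by that p after their values were seen. A negative sign means levels higher with Tau-K174Q and Tau-S199E than the other constructs would give by addition: AKT1 (chromosome 14, 104769349 to 104795751, minus strand, GRCh38) had standardised values of -1.45 ± 0.51 with Tau-WT, 0.78 ± 0.18 with Tau-K174Q, 0.72 ± 0.16 with Tau-S199E and -0.06 ± 0.58 with Tau-K174Q-S199E (SD, n = 3 each). Of the 1676 genes, 886 had a negative and 790 a positive sign. In the ordinary linear model fitted with limma, 1625 genes passed an adjusted p of 0.05, 863 negative and 762 positive, which follows from the selection and is no separate evidence. Moderated variances called 1676, against a mean of 1671.7 in simulated tables that kept each gene's interaction and held no other effect.

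Among genes with a symbol that also passed in the limma fit of the interaction, the largest positive fold changes in the authors' deposited table were those of the read-through gene ZFP91-CNTF (10.61), TMEM160 (5.05), GCHFR, a regulator of tetrahydrobiopterin synthesis (4.45), NDUFS7, a subunit of respiratory complex I (4.25), and XRRA1 (4.22). The largest negative ones among these genes were those of the read-through gene INO80B-WBP1 (-7.64), SGCE, which encodes epsilon-sarcoglycan (-7.11), and the pseudogenes RPL36AP37 (-5.55), HSPE1P4 (-5.39) and RPL7P1 (-5.23). U2AF1 (7.71), the pseudogenes RPL7P9 (-11.49) and PPIAP22 (-5.76), a pseudogene without a symbol (-6.64) and IFITM1 (-6.08) had fold changes of that size but did not pass in limma (adjusted p from 0.0564 to 0.185). Read-through genes and pseudogenes share sequence with other genes, so their values are uncertain where the counting could split reads.

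MAPT, the gene of tau itself (chromosome 17, 45894382 to 46028334, plus strand, GRCh38), was in the table with a log2 fold change of 1.54 and an adjusted p of 0.0115 in the authors' deposited table. Its standardised value was 0.32 ± 0.46 with Tau-WT, -0.52 ± 0.04 with Tau-K174Q, -0.66 ± 0.69 with Tau-S199E and 0.86 ± 1.57 with Tau-K174Q-S199E (SD, n = 3 each). The differences from Tau-WT were -0.84 (SE 0.73), -0.98 (SE 0.73) and 0.54 (SE 0.73), with two-sided exact permutation p = 0.1, 0.1 and 0.8, where 0.1 is the smallest that 3 libraries against 3 can give. The difference of Tau-S199E from Tau-WT was -0.59 without library 12. The interaction of MAPT had an adjusted p of 0.0517 in the limma fit, and passed without library 16 (adjusted p = 0.0345). Library 17 decides the sign of the difference of Tau-K174Q-S199E from Tau-WT, which was -0.29 without it. A 3′ tag may miss a construct that lacks the annotated 3′ end, so these values do not check the transfection.

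The authors grouped the genes into 4 clusters. Clusters 1 (535 genes) and 2 (255 genes) held the genes with a positive sign, and clusters 3 (353 genes) and 4 (533 genes) those with a negative sign. Cluster 4 averaged -0.93 ± 0.19 with Tau-WT, 1.15 ± 0.68 with Tau-S199E and 0.17 ± 0.2 with Tau-K174Q, and cluster 1 averaged 0.97 ± 0.08, -1.11 ± 0.52 and -0.18 ± 0.23. In clusters 2 and 3 the means of Tau-K174Q and Tau-S199E differed by less than the spread between libraries: cluster 3 averaged -1.09 ± 0.18 with Tau-WT, 0.71 ± 0.21 with Tau-K174Q and 0.67 ± 0.49 with Tau-S199E, and cluster 2 averaged 0.86 ± 0.15, -0.62 ± 0.14 and -0.74 ± 0.36 (mean over the genes, SD over libraries, n = 3). For these 8 comparisons with Tau-WT the libraries did not overlap, with a two-sided exact permutation p = 0.1, the smallest possible. Each cluster held genes of 1 sign, and both constructs differed from Tau-WT against that sign in nearly all genes. The separation therefore restates the selection, and this p is no separate evidence. With Tau-K174Q-S199E the cluster means were 0.32 ± 0.81, 0.51 ± 0.82, -0.29 ± 0.86 and -0.39 ± 0.57 in clusters 1 to 4, and its library 18 fell on the side of Tau-K174Q and Tau-S199E in each cluster.

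**Figure D1:**
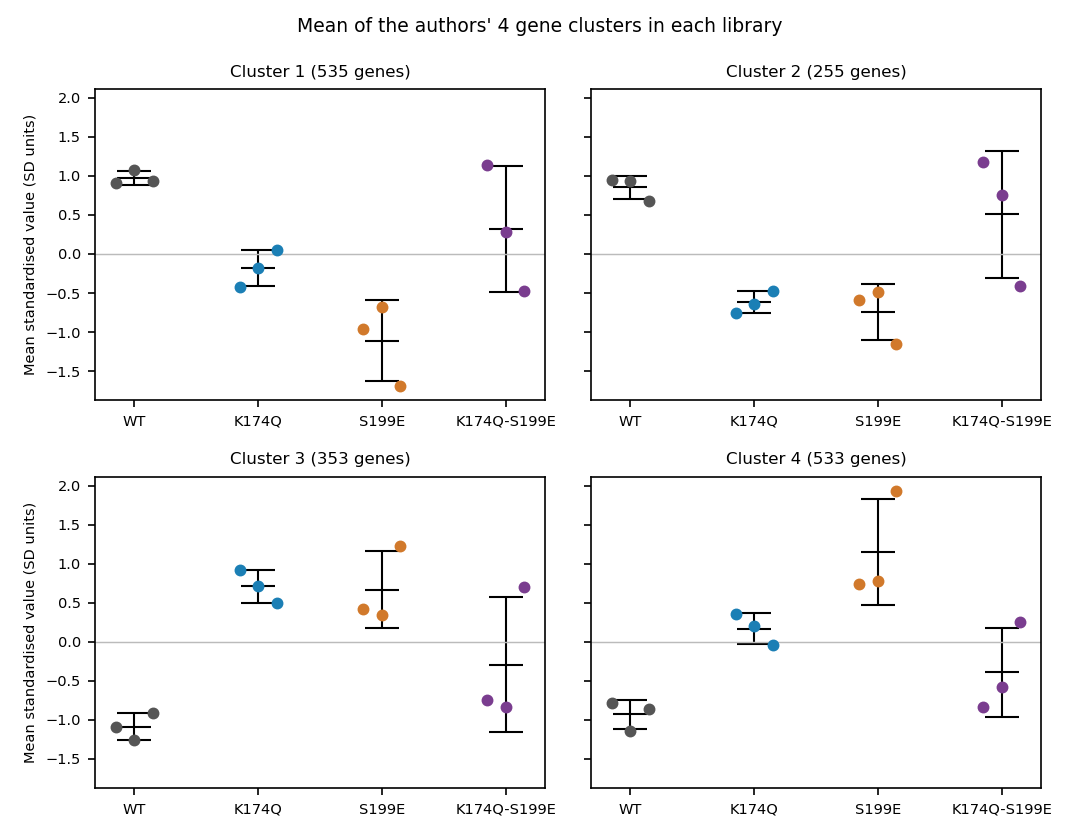
Mean standardised value (SD units) of each of the authors' 4 gene clusters in each library; points are the 3 libraries of a construct, bars the mean and SD. In clusters 1 and 2 the Tau-WT libraries lie above all Tau-K174Q and Tau-S199E libraries and in clusters 3 and 4 below them, while the Tau-K174Q-S199E libraries spread from 1.15 to -0.48 in cluster 1.

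Tau-S199E against Tau-WT asks what the phosphorylation mimic alone does. Of the 1676 genes, 809 rose and 700 fell. The 10 largest rises in SD units were those of MRPS34, a protein of the mitochondrial ribosome (2.59, SE 0.25, adjusted p = 0.00677), the Golgi calcium pump gene ATP2C1 (2.55), TOMM20, a receptor of the mitochondrial import complex (2.54, SE 0.29), OXA1L, which inserts proteins into the mitochondrial inner membrane (2.53, SE 0.32), AURKAIP1, another mitochondrial ribosomal protein (2.53), ZNHIT3 (2.52), PTPRF (2.5), SMDT1, a subunit of the mitochondrial calcium uniporter (2.49), the spliceosomal SNRNP70 (2.49) and the phospholipase gene PLCG2 (2.48). The 10 largest falls were those of the pseudogene YBX1P2 (-2.54), GET3, which delivers tail-anchored proteins to the endoplasmic reticulum (-2.49), the mitotic kinase AURKB (-2.49), the pseudogene RPL12P16 (-2.47), the cytosolic chaperone HSP90AB1 (-2.46), the apoptosis effector BAK1 (-2.46), the autophagy gene ATG10 (-2.45), the sterol synthesis gene NSDHL (-2.44), the pseudogene RHOQP2 (-2.44) and TRIM11 (-2.43), with adjusted p between 0.00687 and 0.00968.

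The sign of the difference between Tau-S199E and Tau-WT equalled that of the interaction in 0 of 1676 genes, and that between Tau-K174Q and Tau-WT in 1 of 1676. How each list below splits into rises and falls with these constructs therefore restates the selection and is no separate evidence, and the camera values against Tau-WT of these constructs are not independent of it either. Of the 76 genes of the nuclear-encoded oxidative phosphorylation list, 30 were in the table, of which 24 rose and 4 fell with Tau-S199E, 28 adjusted over the list alone. UQCRFS1, the Rieske protein of complex III, rose by 2.43 SD units (SE 0.37), NDUFA8 of complex I by 2.41 (SE 0.41) and NDUFA3 by 2.19. The mean of the list was -0.67 ± 0.3 with Tau-WT, 0.04 ± 0.1 with Tau-K174Q, 0.73 ± 0.45 with Tau-S199E and -0.09 ± 0.18 with Tau-K174Q-S199E (SD, n = 3 each). The list was higher with Tau-S199E than the rest of the table (camera, adjusted p = 0.0275), and this call was lost with an estimated correlation (adjusted p = 0.673) and without Tau-WT library 2 (adjusted p = 0.0539). No other list passed camera in this comparison.

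The mesenchymal or substrate-adherent neuroblastoma genes had 6 of 32 members in the table, and all 6 rose with Tau-S199E (camera adjusted p = 0.225). They included CD44, a hyaluronan receptor (2.11, SE 0.44), S100A6 (2.2) and CCN1, a matricellular protein (1.9, SE 0.47). The list mean was -1.06 ± 0.36 with Tau-WT, 0.91 ± 0.67 with Tau-S199E and 0.5 ± 0.19 with Tau-K174Q (SD, n = 3 each). Tau-S199E library 12 lay far from libraries 10 and 11 in these genes as in the table at large, with an SD over genes of 1.67 against 0.83 and 0.77.

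Lists of protein synthesis moved in both directions with Tau-S199E. Of 30 listed cytosolic ribosomal protein genes 18 rose and 11 fell, with RPS29 at 2.27 (SE 0.45) but RPLP0 at -2.41 and RPL7 at -2.4. Of 22 mitochondrial ribosomal protein genes 14 rose and 7 fell, with MRPL12 at -2.36 and MRPL11 at -2.33. Of 20 genes of ribosome biogenesis and RNA polymerase I 7 rose and 11 fell, among them NCL, which encodes nucleolin (-2.33), NOLC1 (-2.29) and DDX27 (-2.25). Of 21 translation factors 8 rose and 13 fell, with EEF1B2 at 2.33, EIF4H at 2.3 and EIF1 at 2.36. Of 9 genes of the aminoacyl-tRNA synthetase list 4 rose and 4 fell, with AIMP2 at 2.08, EEF1E1 at 1.97 and VARS1 at -2.18. AIMP2 and EEF1E1 are on that list but are not synthetases themselves. The counts adjusted over the list alone were 29, 22, 18, 21 and 8.

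Chaperone and stress genes also split. Of 10 genes of the integrated stress and unfolded protein response 3 rose and 7 fell with Tau-S199E (10 adjusted over the list alone). The endoplasmic chaperone HSPA5 fell by 2.38 SD units (SE 0.45), while the transcription factor XBP1 (2.26, SE 0.5) and the serine synthesis gene PSAT1 (2.13) rose. Of 9 genes of the heat shock response list 4 rose and 5 fell (9 adjusted over the list alone), the falls including the mitochondrial chaperonin HSPD1 (-2.35) and HSPH1 (-2.18). All 4 listed p53 targets passed, FBXO22 at 2.24 and TRIAP1 (-2.07) and AEN (-2.0) among them, as did all 5 DNA repair genes, with RPA2 at -2.3 and PARP2 at -2.31. The hypoxia targets ADM (-1.63) and DDIT4 (1.74) moved apart.

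In metabolism, 5 of 9 glycolytic genes rose and 3 fell (8 adjusted over the list alone), with PFKM at 2.42 (SE 0.38), PGAM1 at 2.28 and HK2 at 2.27. Of 7 cholesterol synthesis genes 5 rose, among them MSMO1 (2.23) and HMGCS1 (2.28), and NSDHL fell (7 adjusted over the list alone). Of the 3 mitochondrially encoded transcripts listed, MT-CO2 (2.4) and MT-CO3 (2.24) rose and MT-ND5 (-2.14) fell. In the cell cycle lists 7 of 10 G1/S genes rose and 2 fell (9 adjusted over the list alone), with RRM2 at 2.39, TYMS at 2.25 and CDCA7 at 2.19, while of 9 G2/M genes 4 rose and 3 fell (7 adjusted over the list alone), with TPX2 at -2.18 and CCNB2 at 1.92.

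Genes close to tau biology were few. Of 36 tubulin and microtubule-associated genes 6 were in the table, of which 4 rose with Tau-S199E, including TUBA1A (2.22), TUBA1B (2.01) and DPYSL3 (2.2), and 2 fell (6 adjusted over the list alone). Of 32 enzymes that phosphorylate, dephosphorylate or acetylate tau and sirtuins 6 were in the table, of which 3 rose and 3 fell (6 adjusted over the list alone): the kinases MARK2 (-2.31) and GSK3A (-2.18) fell and the phosphatase scaffold PPP2R1A (2.16) rose. Of the ubiquitin-proteasome genes 9 of 14 rose and 3 fell (12 adjusted over the list alone), with PSMB6 at 2.33, PSMD11 at 2.15 and PSMB4 at 1.94. Of 7 autophagy and lysosome genes 5 rose and 2 fell (7 adjusted over the list alone), with GLA at 2.23, GABARAPL2 at 2.21 and GABARAP at -1.79. Of 6 abundant nuclear noncoding RNAs 4 rose, with SNHG6 at 2.32, SNHG15 at 2.25 and SNHG5 at 2.23, and 1 fell (5 adjusted over the list alone).

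Immune and signalling lists had few members in the table. The interferon list had 3, of which HLA-B (2.34) and B2M (2.25) rose and HERC5 (-2.42) fell. The inflammatory target TNFAIP2 (1.91) and the immediate early genes DUSP2 (1.99) and JUNB (1.77) rose with Tau-S199E. Of the extracellular matrix list only CDH2, which encodes N-cadherin, was in the table, with a difference of -1.34 that did not pass.

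Of the 1676 genes, 1509 passed in Tau-S199E against Tau-WT. Simulated tables that kept each gene's interaction but held no other effect gave 0 genes in 20 of 20 draws, with genes drawn independently, unlike real genes. That 0 is a reference only if the genes were selected on the interaction, since selection on Tau-S199E against Tau-WT would itself set the 1509. Moderated variances called 1650 genes, against a mean of 1105.4 in the simulated tables. Without library 12 the count was 833, the lowest with any Tau-WT or Tau-S199E library left out.

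**Figure D2:**
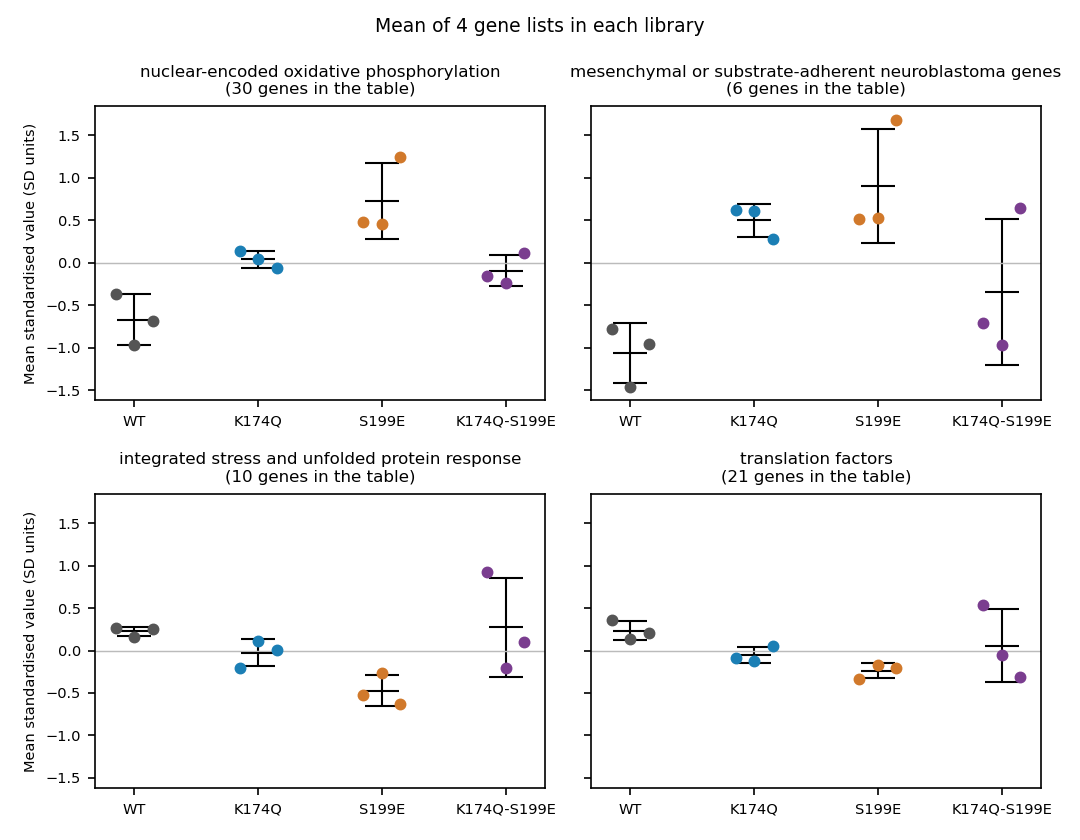
Mean standardised value (SD units) over the listed members of 4 gene lists in each library; points are the 3 libraries of a construct, bars the mean and SD. Oxidative phosphorylation genes averaged -0.67 with Tau-WT and 0.73 with Tau-S199E, and translation factors, whose members moved in both directions, 0.23 and -0.24.

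Tau-K174Q against Tau-WT asks what the acetylation mimic alone does. The genes with the smallest p did not pass and are given as values. Of these, ZZEF1 (2.5, SE 0.35), NKRF, a repressor of NF-kB targets (2.5, SE 0.36), AKT1 (2.23, SE 0.33) and NIF3L1 (2.16, SE 0.34) were higher with Tau-K174Q. GRPEL2, a mitochondrial co-chaperone (-2.33, SE 0.37), the pseudogene RPL12P16 (-1.77), STXBP3 (-2.34), the ubiquitin ligase RNF168 (-2.13) and TMEM18 (-2.31) were lower, all with an adjusted p of 0.066. Of the 30 oxidative phosphorylation genes 24 were higher and 6 lower than with Tau-WT (0 adjusted over the list alone, camera adjusted p = 0.394). All 6 mesenchymal genes were higher (4 adjusted over the list alone, camera adjusted p = 0.247).

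No gene passed for Tau-K174Q against Tau-WT in the limma fit over 12 libraries, although 870 had an unadjusted p under 0.05 and the libraries of the groups did not overlap in 1353 of 1676 genes (80.7%, against 10% by chance and with selection in its favour). The same model on only the 6 libraries compared called 819 genes, against at most 11 in the simulated tables, and limma with moderated variances called 1004, 585 higher and 419 lower, against a mean of 1106.8 in the simulated tables. Without libraries 12 and 18 the count was 981. The 11 is a reference only if the genes were selected on the interaction, and the simulated genes were drawn independently, unlike real genes. Selection on Tau-S199E against Tau-WT was not simulated for the fit on 6 libraries. The 819 therefore does not by itself show an effect beyond selection.

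The differences of Tau-K174Q and Tau-S199E from Tau-WT went the same way in 99.9% of the genes, with a correlation across genes of 0.93 (genes are not independent replicates). Simulated tables with selection on the interaction and the shared Tau-WT libraries, and no other effect, gave 98.7% and 0.91, so that neither value bears on a shared response. The covariance was 2.51 against 1.92 simulated, a difference of 0.59. The 3 Tau-WT libraries were not split, since each part would not keep at least 2, and part of the excess may come from them.

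Tau-K174Q against Tau-S199E is orthogonal to the interaction, but its sign equalled that of the interaction in 1416 of 1676 genes (84.5%). The oxidative phosphorylation list, of which 24 of 30 members had a negative interaction, went the way of most genes with that sign. Selection on the interaction alone does not set this direction, and its source was not tested. The direction leans in part on Tau-S199E library 12. With each gene turned to the sign of its interaction, that library averaged -1.59 over the genes, against -0.72 and -0.61 in libraries 10 and 11. Of the 30 members 22 were lower with Tau-K174Q, with a median difference of -0.88 SD units (camera, adjusted p = 0.000975; adjusted p = 0.793 with an estimated correlation; 2 members adjusted over the list alone). The read-through gene INO80B-WBP1, at -0.54 ± 0.02 with Tau-K174Q and 1.6 ± 0.57 with Tau-S199E (SD, n = 3), was the 1 gene that passed (-2.15, SE 0.24, limma adjusted p = 0.0303). Next came MRPS34 (-1.61, SE 0.25), AURKAIP1 (-1.75), COL8A1, a collagen gene (-1.59, SE 0.26), and PSMB6 (-1.9) on the lower side, and AKR7A2 (1.81), RPA2 (1.86), LITAF (1.53), MAF1, a repressor of RNA polymerase III (1.77), and ATMIN (1.58) on the higher side, which did not pass (adjusted p from 0.0936 to 0.196). The unadjusted p was under 0.05 in 269 genes, and moderated variances called 0 genes; the simulated tables gave 0 and a mean of 0.1. Without Tau-K174Q library 4, 5 or 6 or Tau-S199E library 10, 0 genes passed.

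Tau-K174Q-S199E against Tau-WT, also orthogonal to the interaction, asks whether the mimics together differ from Tau-WT. Its sign equalled that of the interaction in 134 of 1676 genes (8.0%), so most genes went against it. These signs are not independent over genes and lean on library 18. With each gene turned to the sign of its interaction, library 18 averaged -0.44 over the genes. Libraries 16 (0.97) and 17 (0.57) lay near those of Tau-WT (0.91, 1.11 and 0.87). No gene passed in limma with ordinary or moderated variances, while 127 and 156 genes had an unadjusted p under 0.05. The genes with the smallest p, given as values that did not pass (adjusted p = 0.533), were MRPS34 (1.17, SE 0.25), TOMM20 (1.35, SE 0.29), GNPTAB (1.87), AKT1 (1.39, SE 0.33) and AHRR (1.66) on the higher side and RPL12P16 (-1.65), SSRP1 (-1.57), HSP90AB1 (-1.42, SE 0.37), RUBCN (-1.66) and YBX1P2 (-1.15) on the lower side. Most genes with a negative interaction were thus higher with Tau-K174Q-S199E, a direction that selection on the interaction alone does not set. The oxidative phosphorylation list was also higher, in 27 of 30 members, with a median difference of 0.66 SD units (camera, adjusted p = 0.014; adjusted p = 0.746 with an estimated correlation; 0 members adjusted over the list alone). This call was lost without Tau-WT library 2 (adjusted p = 0.167) or 3 (adjusted p = 0.0505) and without Tau-K174Q-S199E library 16 (adjusted p = 0.0766) or 17 (adjusted p = 0.0747).

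Tau-K174Q-S199E against Tau-S199E asks what K174Q adds to S199E. INO80B-WBP1 fell from 1.6 ± 0.57 to -0.6 ± 0.09 (-2.2, SE 0.24, limma adjusted p = 0.025) and COL8A1 from 1.51 ± 0.36 to -0.49 ± 0.29 (-2, SE 0.26, limma adjusted p = 0.0448; SD, n = 3), the 2 genes that passed, within the 0 to 4 (mean 0.2) that the simulated tables gave from selection alone. RAB2A (-2.17), PSMB6 (-1.89) and MRPS34 (-1.42, SE 0.25) were lower and AKR7A2 (1.92), LITAF (1.84), ZBTB8A (2.09), ZNF714 (2.19) and DYNC2I2 (1.98) higher without passing (adjusted p = 0.0644). In 946 genes the unadjusted p was under 0.05. Without Tau-K174Q-S199E library 18 the count was 1315, and without libraries 12 and 18 it was 730. It was 0 without library 10, 0 without library 16 and 6 without library 11. Moderated variances called 1153 genes, 576 higher and 577 lower, near the 1112.9 that selection alone gave.

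Tau-K174Q-S199E against Tau-K174Q asks what S199E adds to K174Q. The genes with the smallest p were NCBP1, a subunit of the nuclear cap-binding complex (2.39), NRP1, a semaphorin co-receptor (2.29), AL031777.3 (1.92), GRPEL2 (1.54) and DNAJC11 (1.69) on the higher side and ACTR10 (-1.56), ZZEF1 (-1.31), TNFAIP8 (-1.88) and MRPS11 (-1.54) on the lower side, with adjusted p from 0.405 to 0.456. No gene passed in limma, 138 had an unadjusted p under 0.05, and moderated variances called 2 genes, against a mean of 1121.4 in the simulated tables. Without library 18 the count was 142, and without libraries 12 and 18 it was 451.

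Over all 4 constructs 566 genes differed in the limma F test. Simulated tables with selection on the interaction and no other effect gave 0 genes. Those with selection on Tau-S199E against Tau-WT gave 452 to 623, so the 566 depends on which selection is assumed. The count fell to between 0 and 5 genes without Tau-WT library 1, 2 or 3, Tau-K174Q library 4, 5 or 6, Tau-S199E library 10, 11 or 12 or Tau-K174Q-S199E library 17, and rose to 783 without library 16 and 1385 without library 18. Moderated variances called 1675 genes, against a mean of 1671.1 in the simulated tables, and centring each library on its median left 9.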

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

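All tests in this part were chosen after the results were seen, except those of GC content for library 18, whose prediction was written before its value was computed. The effect of K174Q depended on S199E in 1625 of 1676 genes by the interaction term in limma. That is what flagged it, and if, as inferred here, the genes were selected on the interaction, the count is set by the selection. For the same reason random splits say nothing here: of 100 splits of the 12 libraries into 4 groups, the real one included, 1 gave as many genes (real 1625, highest other 0), but the real split chose the genes. Over all 4 constructs 2 of 100 splits gave as many (real 566, highest other 614), which the same selection leaves without meaning for chance. For Tau-S199E against Tau-WT 1 of the 10 splits gave as many genes (real 1509, highest other 0). For Tau-K174Q-S199E against Tau-S199E 1 of 10 did (real 2, highest other 0), and for Tau-K174Q against Tau-S199E 1 of 10 (real 1, highest other 0). For Tau-K174Q against Tau-WT (real 0, highest other 0), Tau-K174Q-S199E against Tau-WT (real 0, highest other 2) and Tau-K174Q-S199E against Tau-K174Q (real 0, highest other 0) all 10 of 10 did. With 10 splits no share under 0.05 can be reached.

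The libraries of Tau-K174Q-S199E did not lie together. A score per library, the mean standardised value over the 1676 genes after turning each gene to the sign of its interaction, was 0.97 in library 16 and 0.57 in library 17, near the Tau-WT libraries (0.91, 1.11 and 0.87), but -0.44 in library 18, among those of Tau-K174Q (-0.55, -0.37 and -0.15) and Tau-S199E (-0.72, -0.61 and -1.59). The simulated tables with selection on the interaction put library 18 at 0.69. Their noise was independent between genes, which leaves such a mean over genes little room to vary. Real genes moved together, so the 0.69 does not show where selection alone would put the library. A swap of labels with a Tau-K174Q or Tau-S199E library would need a partner out of place, but each of those 6 libraries correlated across genes above 0 with the others of its construct (lowest 0.41) and below 0 with libraries 16 and 17 (highest -0.24). The selection favours this order, but did not keep library 18 with its group. GC content of the longest transcript of each gene does not account for it either: with each library centred within 20 bins of it the score of library 18 was -0.42. The kit reads near the 3′ end, and the GC content there was not measured. A single wrong label or a swap with an outside sample stays open, since library 18 correlated with those 6 libraries across genes at 0.55 on average, as they did with each other (0.47), and so does a real response that differed between transfections, which no test here addressed.

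Tau-S199E libraries lay farther from Tau-WT than Tau-K174Q libraries did, by -0.62 in the mean score. Library 12 alone is a candidate cause. Without it the difference was -0.31 (SE 0.16), under 2 standard errors, so library 12 and an effect of the construct cannot be told apart.

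The 46 pseudogenes had a median absolute log2 fold change of 2.53 in the authors' deposited table, against 1.34 for the other 1630 genes (permutation p = 1e-05, two-sided, the smallest that 100000 resamples can give), and 7 of the 20 largest fold changes were those of pseudogenes. The parent gene was in the table for 20 of them. A fixed share of the parent gene reads cannot account for the 7 that went against their parent, with correlations over the 12 libraries from -0.85 to -0.56, among them RPL7P9 (log2 fold change -11.49, parent RPL7 0.49). For the 13 that went with it (correlations from 0.45 to 0.98) a fixed share would give at most the fold of the parent, but all 13 had a larger absolute log2 fold change, by a median of 2.11 (from 0.20 to 4.52; mean over the 10 parents 1.92, SE 0.36), so it does not account for the larger size by itself either. Low read counts, which can widen fold changes among genes selected by p, stay open, since the table holds no levels. The near-identical pair U2AF1 (log2 fold change 7.71) and U2AF1L5 went apart, with a correlation of -0.80, so reads moved between copies may also contribute. No biological explanation was tested.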

How the results depend on the processing

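Leaving out libraries 12 and 18, moderated variances, centring on the library median and protein-coding genes only were chosen after the data were seen. Of those chosen before, another scaling factor, filters on low counts, count models, weights for counts and another pseudocount were not run, because standardised values hold no counts or levels. No paired analysis was possible because the columns carry no replicate number. The depth is unknown, so what it limits cannot be stated. The cause of the changes below was not tested.

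Libraries were left out 1 at a time, here and below, only from the constructs compared. Genes passing then ranged from 833 to 1402 for Tau-S199E against Tau-WT, 1273 to 1628 for the interaction and 0 to 1385 for any construct. For Tau-K174Q-S199E they ranged from 0 to 2 against Tau-WT, 0 to 142 against Tau-K174Q and 0 to 1315 against Tau-S199E. They ranged from 0 to 1 for Tau-K174Q against Tau-S199E and stayed at 0 for Tau-K174Q against Tau-WT. Libraries outside a pair also set its residual variance, and leaving these out singly was not run. On only the 6 libraries compared, 819 genes passed for Tau-K174Q against Tau-WT, 0 for Tau-K174Q-S199E against Tau-S199E and 0 for Tau-K174Q against Tau-S199E. With moderated variances the counts were 1004 for Tau-K174Q against Tau-WT, 2 and 1153 for Tau-K174Q-S199E against Tau-K174Q and Tau-S199E, 0 for Tau-K174Q against Tau-S199E and 1675 for any construct, and all 1509 genes of Tau-S199E against Tau-WT remained among 1650. Without libraries 12 and 18 they were 981, 451, 730, 2 and 988 in the same order, and 1301 of the 1509 genes remained among 1331. Centring gave 1 gene for Tau-K174Q-S199E against Tau-S199E and 9 for any construct. Protein-coding genes only moved no count by over 1.5 times.

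Lists passing for Tau-S199E against Tau-WT were 0 with an estimated correlation and 0 to 1 with a library left out. With fry they were 12, but fry sets a list against no change and not against the rest of the table, in which 1509 of 1676 genes passed. For Tau-K174Q-S199E against Tau-WT they were 0 with an estimated correlation, 0 with fry and 0 to 2 with a library left out, and 2 without libraries 12 and 18. For Tau-K174Q against Tau-S199E they were 0 with an estimated correlation and 0 with fry. For the interaction fry gave 9. The difference of MAPT between Tau-S199E and Tau-WT, -0.98, ranged from -1.23 to -0.59 with a library left out, the latter without library 12, and was -1.52 with centring. That between Tau-K174Q-S199E and Tau-WT ranged from -0.29 to 1.27 and that between Tau-K174Q and Tau-S199E from -0.26 to 0.39 with a library left out, and the latter was -0.26 without libraries 12 and 18. With moderated variances MAPT passed in the interaction (2.37) and in Tau-K174Q-S199E against Tau-S199E (1.52), and it passed in the interaction also with centring (3.04) and without library 16 (3.09). With a library left out the interaction of MAPT ranged from 1.53 to 3.09 and its difference between Tau-K174Q-S199E and Tau-S199E from 0.68 to 2.25, both lowest without library 17 and highest without library 16. Of the other 87 genes named for Tau-S199E against Tau-WT 75 kept their direction and side of the threshold in every alternative, 72 of 82 did for the interaction, 10 of 10 for Tau-K174Q-S199E against Tau-WT, 9 of 10 for Tau-K174Q against Tau-S199E, 3 of 10 for Tau-K174Q-S199E against Tau-K174Q, 0 of 10 for Tau-K174Q against Tau-WT and 0 of 10 for Tau-K174Q-S199E against Tau-S199E, where 0 of 10 did so over the settings that leave a library out. None of the named genes other than MAPT changed sign.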

Other observations

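All tests in this part were chosen after the table was seen, though the prediction for chromosomes was written before its result. The table held none of the 36 noradrenergic neuroblastoma and neuronal genes, none of the 34 synapse and ion channel genes and none of the 37 replication-dependent histone genes of the fixed lists. In contrast 30 of 79 cytosolic ribosomal protein genes, 30 of 76 nuclear-encoded oxidative phosphorylation genes, 21 of 50 translation factors and 14 of 34 ubiquitin-proteasome genes were listed. The genes that could have been listed are unknown, so these shares were not tested. Of the 30 oxidative phosphorylation genes 24 had a negative interaction (80%), against 52.9% of the table (Fisher's exact test, p = 0.0027, adjusted p = 0.051 over 19 lists), and so did all 6 mesenchymal genes (p = 0.033, adjusted p = 0.31). The latter comprised TWIST2, SNAI2, LUM, CD44, CCN1 and S100A6, with log2 fold changes in the authors' deposited table of -1.71, -2.46, -3.36, -1.23, -3.47 and -1.73. Fisher's test counts genes as independent, but the estimated correlation between members was 0.23 for oxidative phosphorylation and 0.78 for the mesenchymal genes. Camera with an estimated correlation gave an adjusted p of 0.747 for each of these lists in the interaction.

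CREBBP, an acetyltransferase that can acetylate tau, had a log2 fold change of 1.4 in the authors' deposited table (adjusted p = 0.00709), OGT, which attaches N-acetylglucosamine to serine and threonine, -2.09 (adjusted p = 0.00774) and the deacylase SIRT5 -1.75 (adjusted p = 0.0342). The stress transcription factors ATF4 and DDIT3 stood at 1.28 (adjusted p = 0.00321) and 1.32 (adjusted p = 0.00419). All but DDIT3 and OGT were singled out after their values were seen.

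The first principal component held 74.9% of the variance of the table and ordered the libraries as the score per library did. The second held 6.1%.

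Direction was uneven over chromosomes (permutation p = 0.019 over 20 chromosomes with at least 20 genes). The most uneven was chromosome 19, where 71 of 106 genes (67.0%) had a positive interaction. A shift of whole chromosome copies between cultures would move nearly all genes of a chromosome together. No chromosome with at least 20 genes came above 67.0% in either direction, so such a shift does not account for the pattern on these chromosomes. Chromosomes with fewer genes were not examined. A shift of part of a chromosome, or in part of the cells, was not tested. Genes with a positive interaction had a median GC content of 51.5% and those with a negative interaction of 47.7%, and the genes on chromosome 19 of 59.4%. The shares of positive genes in 20 bins of GC content predicted 61.7 positive genes of the 106. These shares were counted over all genes, chromosome 19 included, which draws the prediction towards the 71. GC content may account for part of the 71, but how much cannot be told from this value.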
